A study of Homo sapiens with 3 samples.

How the data were processed

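Gene expression was measured in MDA-MB-231 cells, a human triple-negative breast cancer line, after transfection with small interfering RNAs (siRNAs) for 48 hours. There were 3 Affymetrix arrays. A single array held RNA of cells given control siRNA (siControl), and 2 arrays held RNA of cells given siRNAs against the long non-coding RNA TMPO-AS1 (siTMPO-AS1 #1 and #2, 1 array each). Biotin-labelled cRNA was made from 150 ng of total RNA, per the labels' protocols. Nothing in the labels says whether the arrays came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical and also holds differences between the 2 siRNAs.

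The deposited values are log2 signals, 1 per probe set and array, made by the authors with RMA (background correction, quantile normalization and summary of probes) in Affymetrix Expression Console, per the submitters' processing notes. Their versions, and the annotation and genome build used, are not given in the sources used here, so no genome positions are printed. On all 3 arrays 1144 of 138745 probe sets (0.825%) had values above 16, the log2 of the brightest value a 16-bit scan can record. A further transformation of the signal is therefore possible, and folds are those of the deposited scale. The array medians were 3.73 (siControl), 3.75 (siTMPO-AS1 #1) and 3.75 (siTMPO-AS1 #2). Arrays have no read depth, and the number of arrays limits the precision. No array repeated another: pairs of arrays shared 6, 7 and 13 identical values.

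Probe sets were named through the platform annotation supplied with the series. Exactly 1 gene symbol was paired with 36176 probe sets, several symbols with 1119, and none with 101450 (unnamed here, which does not mean that they have no gene). Of the 36176, the gene identifiers of 25516 matched a RefSeq gene table (assembly GRCh38.p14), which changed 0 symbols and supplied gene types. Of 33616 genes, 1576 had more than 1 probe set, and the probe set with the highest mean stood for the gene. Genes were tested when their mean over the 3 arrays was at or above the median of the gene-level means, a log2 signal of 4.42, which left 16808. Pseudogene probe sets may also capture RNA of their parent genes.

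All comparisons used the deposited values without further normalization. Both siTMPO-AS1 arrays were compared with the control array with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom, the prior had 3.28, and the prior SD was 0.41. The spread came from the difference between 2 different siRNAs, so it holds effects particular to either siRNA as well as array noise, and the lone control array was assumed to vary like them. Each siRNA against the control is a value with no test. A rule of size was therefore used too: at least 1.5-fold from the control, in the same direction, on both siRNA arrays. Since both log2 ratios share the control array, counts and correlations for no change were obtained from 100 simulations of unchanged arrays sharing 1 control. Their noise was taken from the difference between the siRNA arrays, which also holds any real difference between the siRNAs.

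Gene lists, 21 in number, covered the cell cycle (DNA replication and E2F targets, mitosis, CDK inhibitors), TGF-beta signalling, p53 targets, apoptosis (pro- and anti-apoptotic genes), interferon and NF-kB responses, epithelial and mesenchymal markers, the unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, ribosomal proteins, the respiratory chain, reference genes, luminal, fibroblast and immune markers, and neighbours of TMPO. They held 475 distinct genes, of which 431 had a gene-level value and 372 were tested. Each list was described by its median log2 ratio, by the percentile of that median among 10000 random lists of the same size matched on brightness, and by limma's camera with a preset correlation of 0.01, adjusted over the 20 lists with enough members. Camera p-values with the preset correlation compare list members with the other genes of these arrays and take genes as nearly independent. They do not measure the spread between cultures. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. A list of replication-dependent histone genes was added afterwards.

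The named genes were TMPO-AS1 and TMPO, and, among genes past 1.5-fold with both siRNAs, the 12 higher and the 12 lower with the largest value of the smaller of their ratios. From each list up to 4 members with the largest such value were named, and, for the difference between siRNAs, the 6 genes highest and the 6 lowest with siTMPO-AS1 #1. Symbols starting with LOC, LINC or MIR, or containing a period, were counted but not named. NEDD1, APAF1, CD68, TYROBP, MCM2, MCM5, MCM7, CCN1, CCN2, FN1 and the parent genes ARPC3 and CDC27 are named outside this rule. They were chosen after their values were seen, as were the histone genes and the other genes so described in the closing section.

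The procedure was tested on simulated data for these 3 arrays, with 200 of 16808 genes changed, in 20 runs. The noise was equal on all 3 arrays and drawn from limma's prior, which rests on the difference between the siRNA arrays. It therefore holds any real difference between the siRNAs, and the shares called hold for that noise only. limma then called 0% of genes changed 2-fold, 0% of those changed 4-fold and 0% of those changed 16-fold, although 97.3% of changed genes had the right direction. With the noise multiplied by 0.1, 98.7%, 99.9% and 99.9% were called. A list of 40 genes shifted by 0.7 was called by camera in 20 of 20 runs with independent genes, and 0.05 of 19 unchanged lists were called per run. The alternatives tried were no filter and a stricter filter on dim genes, quantile normalization, centring on the median, the mean of a gene's probe sets, other forms of limma, all probe sets, other folds, each siRNA alone, a rank correlation, and camera with an estimated correlation, on ranks, or replaced by fry. Tables were handled with pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.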

Results

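The expression arrays addressed which transcripts differ in MDA-MB-231 breast cancer cells once TMPO-AS1 is targeted by siRNA. TMPO-AS1 is a long non-coding RNA whose gene lies next to TMPO, the gene of the nuclear envelope protein thymopoietin (lamina-associated polypeptide). Control cells were represented by 1 array and targeted cells by 2 arrays, 1 for each of siTMPO-AS1 #1 and #2. A log2 ratio below is the signal of an siRNA array minus that of the control array. No siRNA had a replicate array.

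The targeted transcript had a lower signal on both siRNA arrays, by little. TMPO-AS1 had a log2 signal of 4.83 in control cells, 4.37 with siTMPO-AS1 #1 and 4.28 with siTMPO-AS1 #2, so that the log2 ratios were -0.46 and -0.55. Both are smaller than the SD of the ratios over all genes tested, 0.80 and 0.59, and both siRNA signals lie under the brightness filter of 4.42. TMPO was also lower, with 14.28 in control cells against 13.39 and 13.76 (log2 ratios -0.89 and -0.52). IKBIP, another neighbour, had log2 ratios of -0.77 and -0.90. NEDD1 (-0.97 and 1.07) and APAF1 (1.09 and -0.70) went opposite ways with the siRNAs. In limma the mean log2 ratio of TMPO-AS1 was -0.51 (SE 0.44, adjusted p = 1.00, lower on 2 of 2 arrays). The SD between the siRNA arrays was 0.062, so the SE was set mainly by the prior that limma shares over all genes, and on simulated data this fit called 0% of 2-fold changes. The list of TMPO and its neighbours, with 4 of 6 genes tested, had medians of -0.83 and -0.61 and was not called (camera adjusted p = 0.162). The median of its mean ratios was -0.33 (percentile 13.2 of random lists), and 0.052 with no filter on dim genes.

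Among genes higher with both siRNAs, CLEC2B, a C-type lectin-like receptor ligand, stood 12.1-fold and 7.60-fold above control (log2 ratios 3.60 and 2.93; mean 3.26, SE 0.52). SLC7A5, which carries large neutral amino acids into cells, stood 5.91-fold and 7.61-fold above control (2.56 and 2.93; mean 2.75, SE 0.46). The intraflagellar transport gene IFT46 had log2 ratios of 3.43 and 2.47, and TPRG1L had 2.48 and 2.36. The receptor tyrosine kinase gene EPHA2 had 1.85 and 2.53, and S1PR1, a receptor for sphingosine 1-phosphate, had 2.19 and 1.98. SAMM50, of the machinery that assembles proteins in the outer mitochondrial membrane, had 2.14 and 2.00. The secreted matricellular protein gene CCN3 had 3.25 and 1.84, SH3RF1 had 2.65 and 1.85, LRRIQ1 had 2.84 and 2.05, and the pregnancy-specific glycoprotein gene PSG9 had 2.45 and 1.95. The pseudogene ARPC3P5 had 1.73 and 1.84, and ARPC3, its parent gene in the actin-nucleating Arp complex, had 1.54 and 1.82, so the value of the pseudogene is uncertain.

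Among genes lower with both siRNAs, CAPZA1, a subunit of the protein that caps actin filaments, stood 13.5-fold and 11-fold below control (log2 ratios -3.75 and -3.46; mean -3.60, SE 0.45). XAF1, an interferon-inducible antagonist of the apoptosis inhibitor XIAP, stood 9.46-fold and 6.21-fold below control (-3.24 and -2.64; mean -2.94, SE 0.50). The mRNA decapping enzyme gene DCP2 had log2 ratios of -2.97 and -2.45, and the p53 target CCNG1 (cyclin G1) had -2.59 and -2.30. CD82, a tetraspanin, had -2.29 and -2.51, and ARHGAP5 had -2.82 and -2.17. SKP2, the F-box protein of a ubiquitin ligase that degrades CDK inhibitors, had -2.26 and -1.93. PRDX3, a mitochondrial peroxiredoxin, had -2.08 and -1.95, CREB5 had -3.04 and -2.03, SCARA3 had -2.28 and -2.14, and the deubiquitinase gene MINDY2 had -2.02 and -2.11. The pseudogene CDC27P2 had -2.39 and -2.02, and its parent CDC27 had -2.42 and -1.44, so its value is likewise uncertain.

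**Figure D1:**
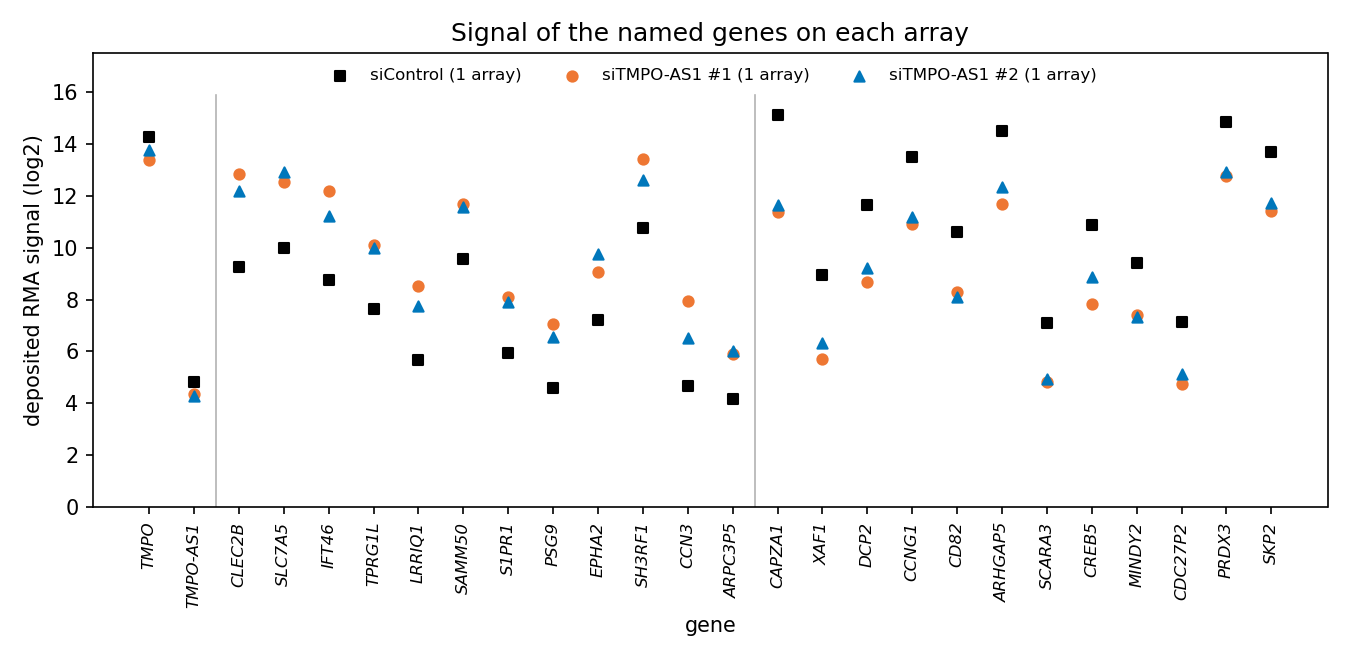
Deposited log2 RMA signal (vertical axis) of TMPO, TMPO-AS1 and the named genes (horizontal axis) on the siControl array (squares), the siTMPO-AS1 #1 array (circles) and the siTMPO-AS1 #2 array (triangles), 1 point per array and no error bars since each condition has 1 array. CAPZA1 lies at 15.12 in control cells against 11.37 and 11.66, and CLEC2B at 9.25 against 12.85 and 12.18.

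Of 16808 genes tested, 911 were at least 1.5-fold higher and 684 at least 1.5-fold lower with both siRNAs, and 554 passed 1.5-fold in opposite directions. At 2-fold the counts were 180 higher and 193 lower. limma called 0 genes at an adjusted p of 0.05, where 261 had an unadjusted p under 0.05, fewer than the 883 of simulated data with nothing changed, and every gene named above had an adjusted p of 1.00. The same count was 0 with an intensity trend in limma. On simulated data with noise set by the difference between the siRNA arrays, limma called 0% of genes changed 16-fold. The count of 0 thus does not show that genes did not differ. Independent lists of the observed sizes would share 449 higher and 330 lower genes, and simulated unchanged arrays that share 1 control had 3280 genes past the rule (3161 to 3417 in 100 simulations). The observed total of 1595 lies below the simulated range, so part or all of it may come from the shared control array. The simulated noise came from the difference between the siRNA arrays, which also holds any real difference between the siRNAs. The simulated count is therefore not a plain chance count and cannot say how much of the total the control array explains.

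DNA replication genes and E2F targets had medians below control with both siRNAs, and further below it with siTMPO-AS1 #1. Of 47 listed genes 43 were tested, and their median log2 ratio was -1.14 with siTMPO-AS1 #1 and -0.26 with siTMPO-AS1 #2. With both siRNAs 29 lay below control, 11 of them by 1.5-fold or more, and 0 lay above. By 1.5-fold or more, 34 were lower and 0 higher with siTMPO-AS1 #1, against 12 lower and 2 higher with siTMPO-AS1 #2. The helicase genes MCM2 (-0.36 and 0.40), MCM5 (-1.28 and 0.48) and MCM7 (-1.20 and 0.23) lay above control with siTMPO-AS1 #2. The members named next were picked for moving the same way with both siRNAs. MCM6, a subunit of the replicative helicase, had log2 ratios of -1.45 and -1.45, and MCM10, which helps to start replication, had -1.66 and -1.34. The checkpoint mediator CLSPN had -1.13 and -1.63, and GINS3 had -1.33 and -1.09. Camera called the list (adjusted p = 5.68e-11), with adjusted p = 0.658 with an estimated correlation. Its medians lay at percentiles 0 and 0.01 of 10000 random lists.

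Mitotic genes had medians of -0.02 with siTMPO-AS1 #1 and -0.27 with siTMPO-AS1 #2. All 39 of the list were tested, and with both siRNAs 16 lay below control and 1 above. By 1.5-fold or more, 9 were lower and 4 higher with siTMPO-AS1 #1, against 4 lower and 0 higher with siTMPO-AS1 #2. Only 1 gene was 1.5-fold lower with both siRNAs, the spindle motor gene KIF11 (-1.64 and -1.06). KIF11 and the mitotic genes named next were picked for moving the same way with both siRNAs. KIF23 had -1.87 and -0.55, the spindle checkpoint gene BUB1B had -0.66 and -0.54, and the condensin gene NCAPG had -0.67 and -0.53. Camera gave an adjusted p of 0.00935, and adjusted p = 0.658 with an estimated correlation. The 6 CDK inhibitor and pocket protein genes tested had medians of -0.06 and -0.16 and were not called (camera adjusted p = 0.478). The median of their mean ratios was 0.17, their average was -0.15, and the test pointed down. RBL2 in that list had -1.71 and -0.98, CDKN2D had -0.47 and -0.39, and CDKN1C had 0.35 and 0.21.

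TGF-beta signalling genes and their responsive genes were lower with siTMPO-AS1 #1, with a median of -0.71 over 25 of 32 genes. With siTMPO-AS1 #2 the median was -0.07, but members went both ways, 6 lower and 8 higher by 1.5-fold or more. Among the higher were CCN1 (-0.71 and 1.57), CCN2 (-2.87 and 1.56) and FN1 (-0.06 and 1.09). The members named next were picked for moving the same way with both siRNAs. The receptor gene TGFBR1 had log2 ratios of -4.81 and -1.80, the receptor gene TGFBR2 had -1.78 and -0.87, and TGFBI, a secreted matrix protein induced by TGF-beta, had -2.49 and -0.76. SKI, a repressor of SMAD proteins, had 0.75 and 0.87, and was the 1 member higher by 1.5-fold with both siRNAs, against 4 lower. Camera gave an adjusted p of 0.0151, and adjusted p = 0.658 with an estimated correlation. Mesenchymal markers had medians of -0.50 and -0.10 over 16 genes, of which 8 lay below control with both siRNAs and 0 above. By 1.5-fold or more, 7 were lower and 0 higher with siTMPO-AS1 #1, against 5 lower and 3 higher with siTMPO-AS1 #2. With both siRNAs 0 were higher by 1.5-fold and 4 were lower. These were the integrin gene ITGA5 (-1.41 and -2.79), the membrane metalloproteinase gene MMP14 (-1.69 and -1.37), the cadherin gene CDH11 (-1.08 and -1.38) and TGFBI, which both lists hold. Camera gave an adjusted p of 0.00477, and adjusted p = 0.658 with an estimated correlation. Epithelial markers had medians of 0.17 and 0.76 over 11 genes and were not called (camera adjusted p = 0.197), with 0.34 and 2.30 for EPCAM, an epithelial adhesion molecule.

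Anti-apoptotic genes had medians of -0.86 and -0.19 over 8 genes, of which 6 lay below control with both siRNAs and 0 above. By 1.5-fold or more, 6 were lower and 0 higher with siTMPO-AS1 #1, against 1 lower and 1 higher with siTMPO-AS1 #2. Those named next were picked for moving the same way with both siRNAs. BCL2L2, a relative of BCL2, was 1.5-fold lower with both siRNAs (-0.88 and -0.91), BIRC3 had -0.89 and -0.41, CFLAR had -0.84 and -0.23, and BCL2 had -0.76 and -0.20. Camera gave an adjusted p of 0.00935, and adjusted p = 0.658 with an estimated correlation. The call was also lost under a stricter filter on dim genes (adjusted p = 0.137). Pro-apoptotic genes, with medians of 0.46 and 0.05 over 15 genes, were not called (camera adjusted p = 0.505). PMAIP1 (1.43 and 1.17) and BAK1 (0.93 and 0.99) were the 2 members past 1.5-fold with both siRNAs, while BID had -1.53 and -0.57 and BAX had -0.46 and -1.02. p53 targets were not called either (medians -0.16 and 0.03 over 22 genes, camera adjusted p = 0.205), but were under the stricter filter (adjusted p = 0.0261, median of the mean ratios -0.26 against -0.012). MDM2, the ubiquitin ligase of p53, had -3.30 and -1.29, TNFRSF10B, a death receptor, had -1.29 and -1.56, and TRIAP1 had 0.53 and 0.64.

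Hypoxia and glycolysis genes were higher, with medians of 0.42 and 0.30 over 22 genes, 3 of them past 1.5-fold with both siRNAs and 0 lower. The peptide hormone gene ADM had log2 ratios of 3.61 and 1.26, the glycolytic enzyme gene ENO1 had 0.75 and 0.73, EGLN3 had 0.60 and 0.78, and ALDOC had 0.62 and 0.52. Camera gave an adjusted p of 0.0151, and adjusted p = 0.658 with an estimated correlation. Respiratory chain genes had medians of 0.28 and 0.42 over 26 genes, and 20 lay above control with both siRNAs, 2 of them by 1.5-fold, against 0 below. These were ATP5F1A, a subunit of ATP synthase (0.90 and 0.76), and COX7B, a subunit of cytochrome c oxidase (0.61 and 0.86), while NDUFB10 had 0.68 and 0.53 and NDUFA1 had 0.44 and 0.53. Camera gave an adjusted p of 0.00935, and adjusted p = 0.658 with an estimated correlation. Ribosomal protein genes (medians 0.10 and 0.25 over 25 genes) were not called (camera adjusted p = 0.197), and RPS19 had 1.78 and 1.60.

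Stress, inflammation and sterol lists were not called in the main setting. Interferon response genes had medians of 0.25 and 0.19 over 30 genes (camera adjusted p = 0.386), and their members went both ways: the transcription factor gene IRF1 had -2.21 and -1.55, SAMD9 had 0.97 and 1.10, and IFI27 had 0.66 and 0.77. NF-kB and inflammatory genes had medians of -0.83 and 0.11 over 18 genes (camera adjusted p = 0.0701), with -0.86 and -0.31 for NFKB2, -0.30 and -0.71 for LIF and 0.25 and 0.76 for RELB. That list was called under the stricter filter (adjusted p = 0.0491) and with camera on ranks (adjusted p = 0.0409). Unfolded protein and ATF4 response genes had medians of -0.12 and 0.05 over 24 genes (camera adjusted p = 0.478). Besides SLC7A5, its partner in amino acid transport SLC3A2 had 0.58 and 1.08, while XBP1, a transcription factor of that response, had -0.99 and -1.69, and CTH had 0.47 and 0.50. Cholesterol synthesis genes had medians of -0.72 and 0.19 over 19 genes (camera adjusted p = 0.107), with -0.86 and -1.26 for the squalene epoxidase gene SQLE, -1.80 and -0.68 for STARD4, -1.06 and -0.63 for INSIG1 and 0.57 and 0.42 for the lanosterol synthase gene LSS. With both siRNAs 3 members lay below control and 3 above, and the list was called under a stricter filter on dim genes (adjusted p = 0.0491).

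Markers of other cell types and reference genes were not called. Luminal breast markers had medians of -0.07 and -0.08 over 13 genes (camera adjusted p = 0.0903), with -2.42 and -1.39 for SPDEF and 1.41 and 0.36 for GATA3. The median of their mean ratios was -0.37 (percentile 0.74 of random lists) and their average was -0.42. That median was -0.26 with no filter on dim genes (camera adjusted p = 0.185) and -0.14 with the stricter filter (camera adjusted p = 0.382). Fibroblast markers had medians of 0.19 and 0.47 over 5 genes (camera adjusted p = 0.377), with 1.13 and 0.62 for LUM and -0.29 and -0.63 for PDGFRB. Of the immune markers 2 were tested, too few for a list test: CD68 had 1.18 and -0.35, and TYROBP had -0.18 and 0.73. Reference genes had medians of 0.06 and 0.01 over 12 genes (camera adjusted p = 0.478), although TFRC (-2.46 and -0.40) and TBP (-1.80 and -0.49) were lower with siTMPO-AS1 #1. The median of their mean ratios was 0.00, their average was -0.23, and the test pointed down.

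**Figure D2:**
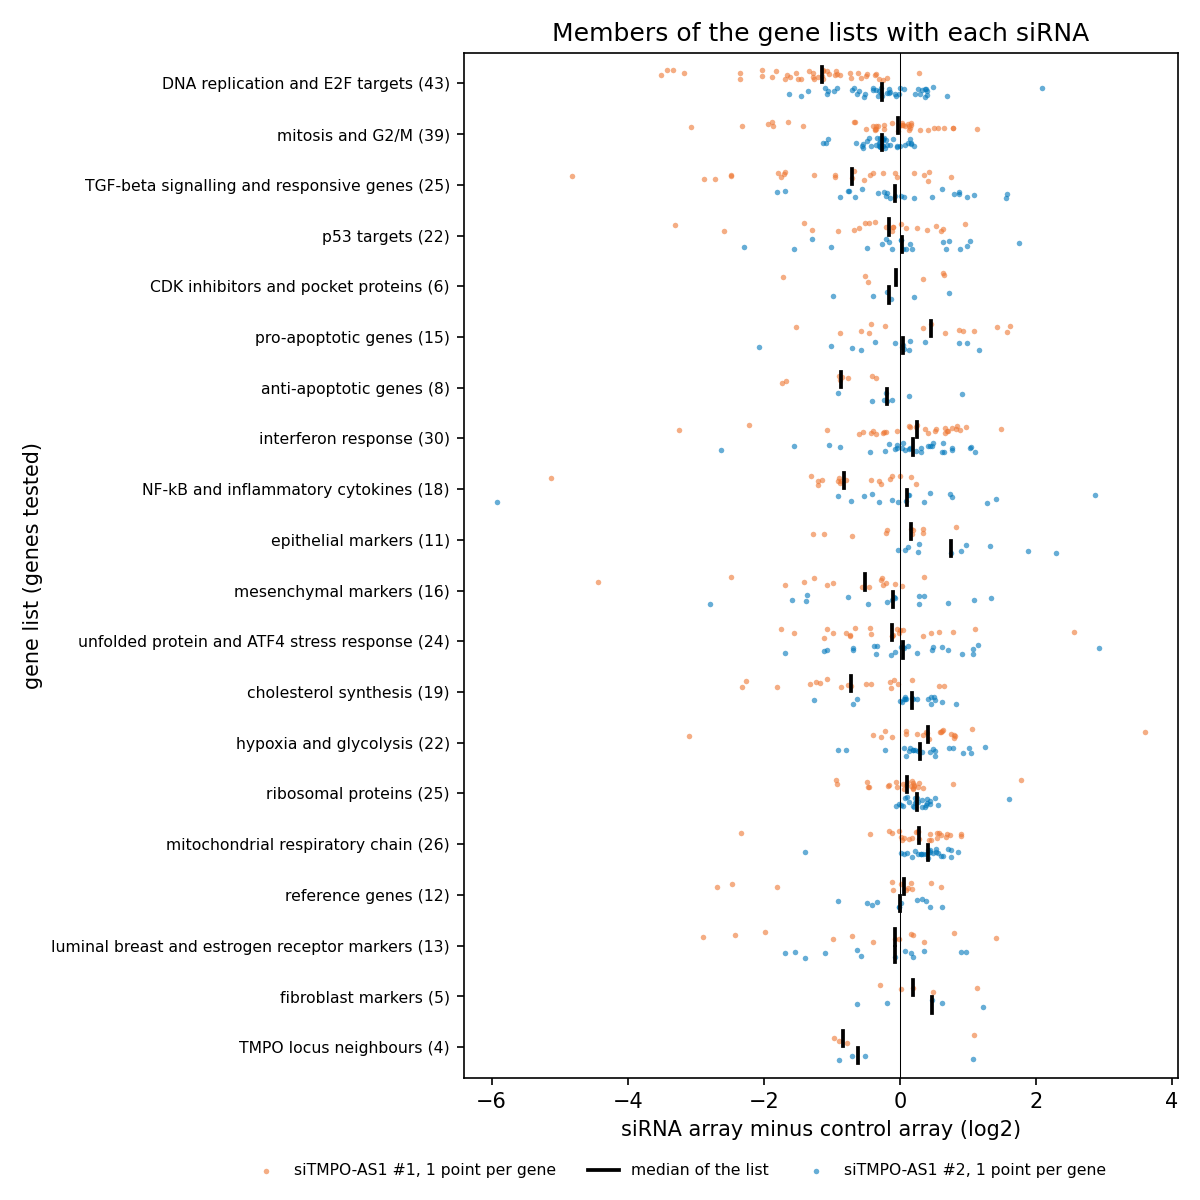
Log2 ratio of each tested member (horizontal axis, siRNA array minus control array) of 20 gene lists (vertical axis, genes tested in brackets) with siTMPO-AS1 #1 (orange) and siTMPO-AS1 #2 (blue), 1 point per gene; black bars are list medians. The bars of DNA replication genes and E2F targets lie at -1.14 and -0.26, and those of the respiratory chain at 0.28 and 0.42.

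In all, camera called 7 of 20 lists, and 0 with an estimated correlation or with fry, which tests whether the members move 1 way. The estimated correlation and fry both rest on 1 residual degree of freedom. The estimated correlations were 0.654 for DNA replication, 0.56 for TGF-beta, 0.5 for anti-apoptotic genes, 0.083 for mesenchymal markers and 0.030 for hypoxia and glycolysis. All of these lie above the preset 0.01. For mitosis and the respiratory chain they were -0.009 and -0.015, below the preset, yet their calls were lost too. With 1 residual degree of freedom neither the estimated correlation nor fry was likely to call any list, so their lost calls do not decide whether a list moved. The preset 0.01 takes genes as nearly independent, so its calls do not settle this either. Apart from the DNA replication list, each called list lay inside the central 95% of random lists with 1 of the siRNAs. The percentiles there were 26.5 for mitosis and 95.2 for the respiratory chain with siTMPO-AS1 #1, and 6.80 for TGF-beta, 8.34 for anti-apoptotic genes, 5.70 for mesenchymal markers and 94.6 for hypoxia and glycolysis with siTMPO-AS1 #2. limma called 0 members of any list, both over all genes tested and when adjusted over the list alone; at an unadjusted p under 0.05 there were 4 in the DNA replication list and 3 among mesenchymal markers.

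The siRNAs also differed from each other. CCL2, a monocyte-attracting chemokine, had a log2 signal of 10.35 in control cells, 10.36 with siTMPO-AS1 #1 and 4.43 with siTMPO-AS1 #2. UGDH (13.93 against 8.33), RRBP1 (12.11 against 6.95), PPIL1 (15.98 against 11.06) and the kinase gene LIMK1 (10.34 against 6.06) were likewise higher with siTMPO-AS1 #1 than with siTMPO-AS1 #2. PPARGC1A, a coactivator of mitochondrial biogenesis, had log2 ratios of 4.55 and -0.45. IGFBP3, an insulin-like growth factor binding protein, had -5.22 and 0.56, the collagen cross-linking enzyme gene LOX had -4.43 and 1.35, MGST1 had -4.90 and 0.86, and P3H2 had -3.91 and 1.67. The imprinted gene MEST (-2.92 and 2.59) and the tight junction gene CLDN1 (-1.90 and 3.54) lay on opposite sides of control.

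Between the siRNA arrays 2499 genes were at least 1.5-fold higher and 3817 at least 1.5-fold lower with siTMPO-AS1 #1, values of 1 array each with no test. Against control, siTMPO-AS1 #1 had 2791 genes higher and 3158 lower by 1.5-fold, and siTMPO-AS1 #2 had 2705 higher and 1754 lower. Across the 16808 genes, which are not independent replicates, the log2 ratios of the siRNAs had a Pearson correlation of 0.245 and a Spearman correlation of 0.279, and 60.8% had the same sign. Simulated unchanged arrays that share 1 control gave a Pearson correlation of 0.50 (0.483 to 0.519) and a covariance of 0.378, against an observed covariance of 0.117. The same simulations gave a Spearman correlation of 0.472 (0.457 to 0.492) and 66.6% of genes with the same sign (66.0% to 67.5%). The noise in the simulation was set by the difference between the siRNA arrays, which also holds any real difference between the siRNAs. The SD of that difference over genes was 0.87, against an SD of the log2 ratios of 0.80 for siTMPO-AS1 #1 and 0.59 for siTMPO-AS1 #2.

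**Figure D3:**
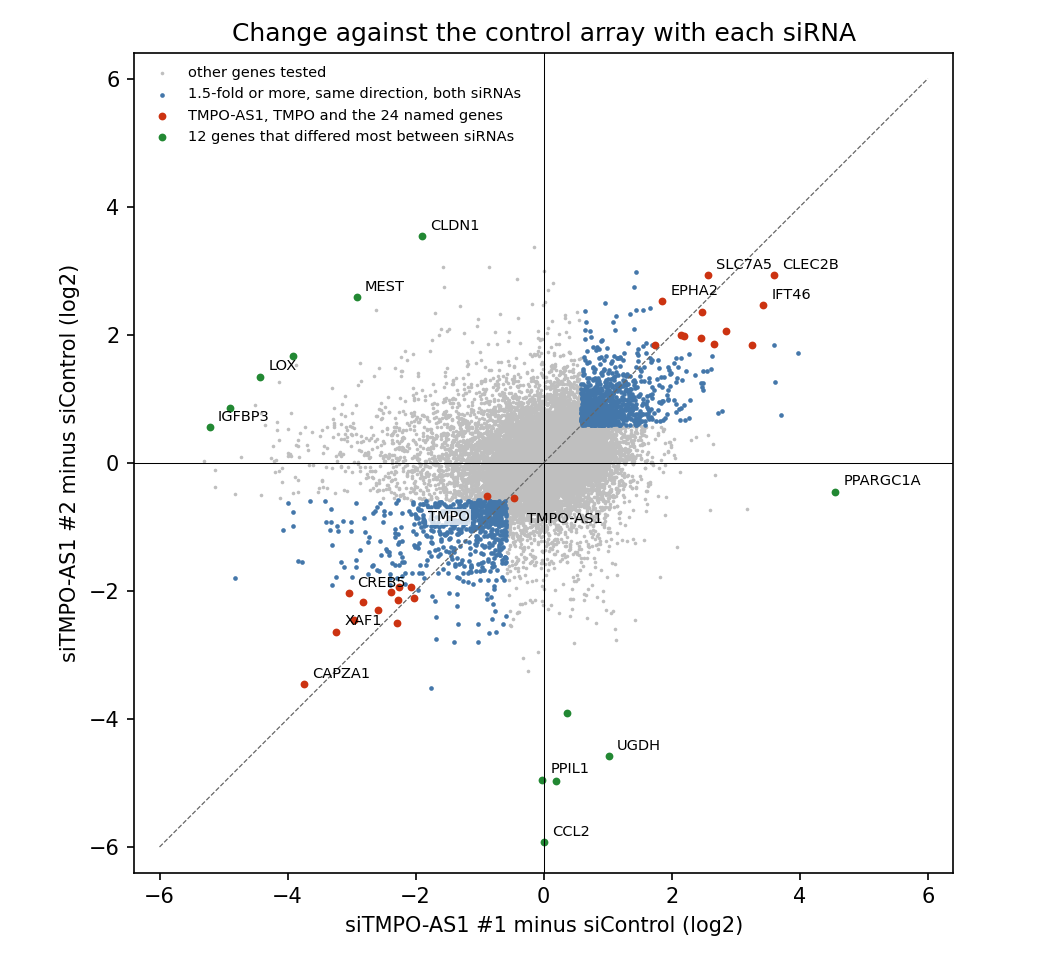
Log2 ratio against the control array with siTMPO-AS1 #1 (horizontal axis) and siTMPO-AS1 #2 (vertical axis), 1 point per gene tested; blue points pass 1.5-fold in the same direction with both siRNAs, red points are TMPO-AS1, TMPO and the 24 genes named for both siRNAs, green points are the 12 genes named for the difference between siRNAs, and the dashed line marks equal ratios. CAPZA1 lies at -3.75 and -3.46 near the line, and CCL2 at 0.01 and -5.92 far from it.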

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

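The values of this part come from probe sets that the comparisons of genes left out; neither was weighed further. Among 30441 probe sets without a single gene symbol that were as bright as the genes tested, 1374 were at least 1.5-fold higher than control with both siRNAs, and 1065 were lower. The share that was higher was 4.51%, against 5.42% of the genes tested.

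The array also carries 23 background probe sets, graded by the number of G or C bases in their probes. The set with 3 such bases was higher with siTMPO-AS1 #2 than in control cells by a log2 value of 1.32, and lower with siTMPO-AS1 #1, at -0.53. The sets with 4 and 5 such bases were also higher with siTMPO-AS1 #2, by 0.73 and 0.66, and differed by -0.10 and 0.42 with siTMPO-AS1 #1. In the 18 sets with at least 8 such bases the largest differences from control were 0.05 with siTMPO-AS1 #1 and 0.15 with siTMPO-AS1 #2.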

How the results depend on the processing

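No test of this part was chosen after the results were seen. No paired analysis was possible because the control has 1 array and each siRNA has 1 array, so no fit with a block can be made. The count of 0 genes called by limma was 0 under all 9 alternatives, and simulated 16-fold changes were called in 0% of cases, so this says nothing about stability. TMPO-AS1 was lower under the 6 alternatives that gave a value, from -0.46 to -0.55; under the stricter filter it was too dim to be tested. Signal near background limits such dim genes.

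Against 1595 genes past 1.5-fold with both siRNAs, 880 passed under the stricter filter, which tests fewer genes, 373 at a fold of 2 and 3291 at a fold of 1.3. With either siRNA alone, which asks for 1 array only, there were 4459 (without siTMPO-AS1 #1) to 5949 (without siTMPO-AS1 #2). The share that was higher stayed between 53.4% and 57.1% under the other scalings and filters. The correlation between siRNAs, 0.245, was 0.294 with no filter, 0.194 with the stricter filter and 0.279 as a rank correlation; the cause was not tested.

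The 7 gene lists called by camera were 0 with an estimated correlation and 0 with fry, which leave the medians over the mean of both siRNAs as they were: -0.69 (DNA replication), -0.14 (mitosis), -0.54 (TGF-beta), -0.51 (anti-apoptotic), -0.41 (mesenchymal), 0.35 (hypoxia) and 0.30 (respiratory chain). Adjusted p = 0.658 with an estimated correlation held for each, and fry gave adjusted p from 0.612 to 0.827. Reference genes, which were not called, also had adjusted p = 0.658 with an estimated correlation and 0.827 with fry. Both settings rest on 1 residual degree of freedom and could hardly call any list. With no filter the mesenchymal median was -0.23, still called. Under the stricter filter the anti-apoptotic median was -0.38 and its call was lost. With either siRNA alone, medians ran from -0.71 to -0.071 for TGF-beta, from -1.14 to -0.26 for DNA replication, from -0.86 to -0.19 for anti-apoptotic genes, from -0.50 to -0.10 for mesenchymal markers and from 0.28 to 0.42 for the respiratory chain, and the shifts nearer 0 among the lower of these lists were those without siTMPO-AS1 #1. For mitosis they were -0.27 without siTMPO-AS1 #1 and -0.020 without siTMPO-AS1 #2. Other scalings, no filter and the mean of a gene's probe sets gave 7 called lists, the stricter filter 9 (p53 targets, NF-kB and cholesterol synthesis gained) and camera on ranks 8 (NF-kB gained).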

Other observations

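All tests of explanations in this part, and the list of histone genes, were chosen after the results were seen. Replication-dependent histone genes, which are transcribed in S phase, were lower with both siRNAs. Of 58 such genes 50 were tested, and their median log2 ratios were -0.70 with siTMPO-AS1 #1 and -0.37 with siTMPO-AS1 #2. With both siRNAs 35 lay below control, 9 of them by 1.5-fold or more, and 4 lay above. H2AC21 had log2 ratios of -1.41 and -1.38, H3C7 had -1.36 and -1.11, H2AC15 had -1.40 and -0.99, and H3C15 had -1.52 and -0.96. Camera gave p = 3.27e-10, and p = 0.321 with an estimated correlation; limma called 0 of the 50, with 2 at an unadjusted p under 0.05. Histone genes are alike in sequence, so probe sets of different members can share signal.

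Some single genes outside the naming rule, chosen after their values were seen, differed widely between the siRNAs. The neutrophil-attracting chemokine gene CXCL8 had log2 ratios of -5.13 with siTMPO-AS1 #1 and -0.11 with siTMPO-AS1 #2, and the cytokine gene IL1B had -0.42 and 2.87. CCN2, a target of TGF-beta and YAP, had -2.87 and 1.56. UHRF1, which maintains DNA methylation, had -1.61 and 2.09, and the sterol synthesis genes HMGCS1 (-2.32 and 0.50) and MSMO1 (-2.26 and 0.25) lay on opposite sides of control. By gene type, 36 small nuclear RNA genes had medians of 0.55 and 0.08, 89 small nucleolar RNA genes 0.21 and 0.06, 620 long non-coding RNA genes 0.04 and 0.00, and 10849 protein-coding genes -0.04 and 0.13.

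The median of the DNA replication list was lower with both siRNAs. A trend with brightness between arrays is argued against, since the list median lay at percentile 0.01 of random lists matched on brightness with the siRNA that moved it less. A candidate explanation is that fewer cells were in S phase. The histone median of -0.52 for the mean of both siRNAs (-0.70 with siTMPO-AS1 #1 and -0.37 with siTMPO-AS1 #2) goes with it. For siTMPO-AS1 #2 the values are mixed: of the replication genes 12 were 1.5-fold or more lower and 2 higher, and MCM2 (0.40) and MCM5 (0.48) lay above control. A control array out of place, for example from cells with more S phase, would enter both list medians (-1.14 and -0.26) by an unknown amount. It cannot be told apart from an effect that the siRNAs share, because there is 1 control array. The TMPO-AS1 signal itself was lower by little (-0.46 and -0.55), and under the brightness filter on both siRNA arrays. Whether the shift follows from less TMPO-AS1 or from other effects of the siRNAs was not tested and remains open.

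The same list was lower with siTMPO-AS1 #1 than with siTMPO-AS1 #2, by a median of -0.88. The control array does not enter this difference. The central 95% of random lists spanned -0.36 to 0.17. An effect particular to either siRNA, or to its culture, was not tested and stays open.

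The log2 ratios of the siRNAs correlated weakly for arrays that share a control. Equal noise on all 3 arrays with no change by either siRNA is argued against, since the correlation of 0.245 lies below the simulated range of 0.483 to 0.519; equal noise together with effects particular to an siRNA is not excluded. Noise independent between genes on the siRNA arrays is argued against too, since 5 of 20 lists had a median difference between siRNAs outside the central 95% of random lists, where chance gives 1. These were DNA replication (-0.88), mitosis (0.24), TGF-beta (-0.81), NF-kB (-1.05) and epithelial markers (-0.77). Effects particular to an siRNA may account for this, as may a difference between cultures, and the design has no replicate of either siRNA to separate them.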
